A study of Mus musculus with 8 samples.

How the data were processed

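Heart RNA was analysed on 8 Affymetrix Mouse Gene 2.0 ST arrays, 5 after injection of digoxin at 1 mg/kg and 3 after vehicle. The titles number the samples within each group, and each array is taken as 1 mouse. Total RNA was amplified, converted to labelled single-stranded cDNA and hybridised. The authors normalised the raw arrays with Robust Multi-array Average in a Galaxy tool suite, per the series design text, and limma is named in the submitters' processing notes. The versions of these tools are not given in the sources used here. The deposited log2 values are centred for each probe set. Column medians lie between -0.0058 and 0.0087, and 21739 of 34351 probe sets hold at least 1 value of exactly 0. The centre is not the median of these 8 arrays, since that median is within 1e-06 of 0 in 7.20% of probe sets. It is taken to be a constant for each probe set, in which case it cancels in every difference between arrays. What it refers to is not stated. The log base is not written with the values and is taken as that of the normalization method. A signal over background cannot be given for centred values.

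Probe sets were named from the platform annotation. Of 34351 probe sets, 23521 had 1 gene symbol, 1814 had several and 9016 had none in that annotation. Entrez identifiers of 23328 matched the RefSeq gene table, and 0 symbols changed. Probe sets with several symbols were not used to name a gene. The plan was to keep for each gene the probe set with the highest mean, and to try filters on dim genes. Both need absolute levels, which centring removes, so the mean over the probe sets of a gene was used, and the filters were not run. This gave 22180 genes, 21098 of them with 1 probe set and 1082 with more.

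Digoxin was compared with vehicle with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), with no covariate. The SE of a log2 change is that of the moderated fit, with 6 residual and 2.75 prior degrees of freedom, and the 95% intervals use their sum. The array numbers in the labels put the vehicle arrays first and the digoxin arrays after them, so array order and treatment cannot be told apart. Values of SD are between arrays. The p values measure the spread between these samples, which the labels number separately.

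Before the data were examined, 26 gene lists and 17 lists of cell type markers were fixed, with 828 members, of which 747 were measured. The 42 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation, fry, and fgsea 1.28.0 with 10000 permutations were run as alternatives. Camera asks whether the genes of a list rank higher or lower than other genes, fry whether they move one way on balance. Marker lists were compared by their mean over members on each array, with an exact two-sided permutation test over all 56 assignments of 3 of the 8 arrays, for which the smallest p is 0.0179. Marker tests were adjusted over 17 lists, and no adjusted value was below 0.52.

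The genes named were also fixed by a rule. They were the 12 largest rises and the 12 largest falls among genes past the test whose groups did not overlap, without predicted, small RNA and olfactory or vomeronasal receptor genes, the 4 members of smallest p in each gene list that passed camera, up to 4 members past the test in each list that did not, and 21 genes whatever their values. These 21 were genes of the clock, the Na/K-ATPase and cardiac stress, together with Cdkn1a, Hif1a and Nlrp3. Of the 21, 17 were tested, and the others are not reported here. In all 72 genes came under the rule. The members of the glucocorticoid list are named in full because the list led the result, and Ciart, Usp2, Wee1, Esam and Eng were named after their values were seen.

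The limma fit and camera, with the settings above, were tested on simulated data made for this comparison over 22180 genes with 200 changed genes. The averaging of probe sets and the permutation test were not part of this simulation. At a log2 change of 0.5, 74% were recovered, at 1 it was 95% and at 2 it was 98%. Of the calls, 8.59% were genes that had not been changed, and 0 genes were called when none was changed. All 20 lists raised by 0.3 were called, and 0 of 40 unchanged lists. The simulated genes were independent, and on the real arrays camera called up to 22 lists when the 8 arrays were split another way, so the simulation does not show how often camera errs here. Alternatives covered the normalization between arrays, the probe sets, the variance model, array weights, the thresholds, the replicate number as a block, and each array left out in turn. Added after the data were seen were genes with 1 probe set alone, protein-coding genes alone, the removal of digoxin replicate 4 and vehicle replicate 3 together, and the atrial marker mean as a covariate. No 2 arrays were duplicates, since the SD of the difference between any pair of arrays was at least 0.12. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.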

Results

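Gene expression was measured in hearts of adult male mice, labelled C57BL6JRj and named C57BL6/J in the growth protocol, after a single intraperitoneal dose of digoxin at 1 mg/kg or of the solvent alone. Digoxin is a cardiac glycoside, a plant-derived drug that inhibits the Na/K-ATPase of the plasma membrane. The injection was given at ZT5 and the hearts were taken at ZT9, both in the light phase, where ZT0 is lights-on. RNA was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, with 5 arrays of digoxin hearts and 3 arrays of vehicle hearts. The design text counts 4 vehicle samples, and the fourth was not analysed here. The values are log2 expression centred for each probe set, so they give differences between arrays and no absolute level. The number of arrays limits the precision of every value.

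The comparison addresses how the heart transcriptome responds to a cardiac glycoside within hours. Since dosing was timed, clock genes and targets of the clock repressor REV-ERB alpha were among the lists fixed before the data were examined. Of 22180 genes tested with limma, 302 changed at the threshold of 0.05 for the adjusted p, and 210 of them rose while 92 fell. This excess of rises was not seen without vehicle replicate 3, where 185 rose and 189 fell. The largest rise was that of Cdkn1a, the cyclin-dependent kinase inhibitor p21, to 4.72 times the vehicle level. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 4.49 times the vehicle level. The largest fall was that of Aplnr, the apelin receptor, whose level in vehicle hearts was 2.21 times that in digoxin hearts.

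In Cdkn1a the centred log2 value was 2.05 ± 0.13 (SD, n = 5) in digoxin hearts and -0.19 ± 0.16 (SD, n = 3) in vehicle hearts, a log2 change of 2.24 with an SE of 0.09 and an adjusted p of 1.8e-05 in limma. Fkbp5 rose by 2.17 (SE 0.09). Arrdc2, an alpha-arrestin, rose by 2.03 (SE 0.13), and Ddit4, an inhibitor of mTORC1 signalling, rose by 1.98 (SE 0.13). Trp53inp1, a p53-inducible nuclear protein gene, rose by 1.90 (SE 0.17). The histone methyltransferase gene Setdb2 rose by 1.65 (SE 0.14), Depp1 by 1.63 (SE 0.11) and the scramblase family gene Plscr2 by 1.62 (SE 0.19). Bcl2l1, which encodes the anti-apoptotic protein Bcl-xL, rose by 1.51 (SE 0.06). The mitochondrial nucleotide carrier gene Slc25a33 rose to 2.83 times the vehicle level (log2 SE 0.08), and the kinase gene Map3k6 and Fam117b both rose by 1.42 (SE 0.06 and 0.11). The adjusted p of these 12 genes lay between 1.8e-05 and 0.0052.

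Among the falls, Aplnr had a log2 change of -1.15 (SE 0.08, adjusted p = 0.00033). Rrad, a small GTPase that restrains L-type calcium channels, followed at -1.12 (SE 0.15). Ppp1r10, a nuclear regulator of protein phosphatase 1, stood at -1.07 (SE 0.08) and the vascular homeobox gene Meox2 at -1.001 (SE 0.16). St8sia4, a polysialyltransferase gene, stood at -0.90 (SE 0.13) and Phlda1 at -0.83 (SE 0.13). The values were -0.70 (SE 0.10) for Tnfsf10, which encodes the death ligand TRAIL, and -0.69 (SE 0.08) for the endothelial gene Myct1. Rassf9 stood at -0.66 (SE 0.08), Gja1, the gene of the gap junction protein connexin 43, at -0.65 (SE 0.09), Neurl3 at -0.64 (SE 0.06) and Cd200 at -0.64 (SE 0.12). The adjusted p of these 12 genes lay between 0.00033 and 0.045. In all 302 genes that changed, the digoxin and vehicle arrays did not overlap. Among all genes tested 8.16% had groups without overlap, against 3.57% by chance.

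**Figure D1:**
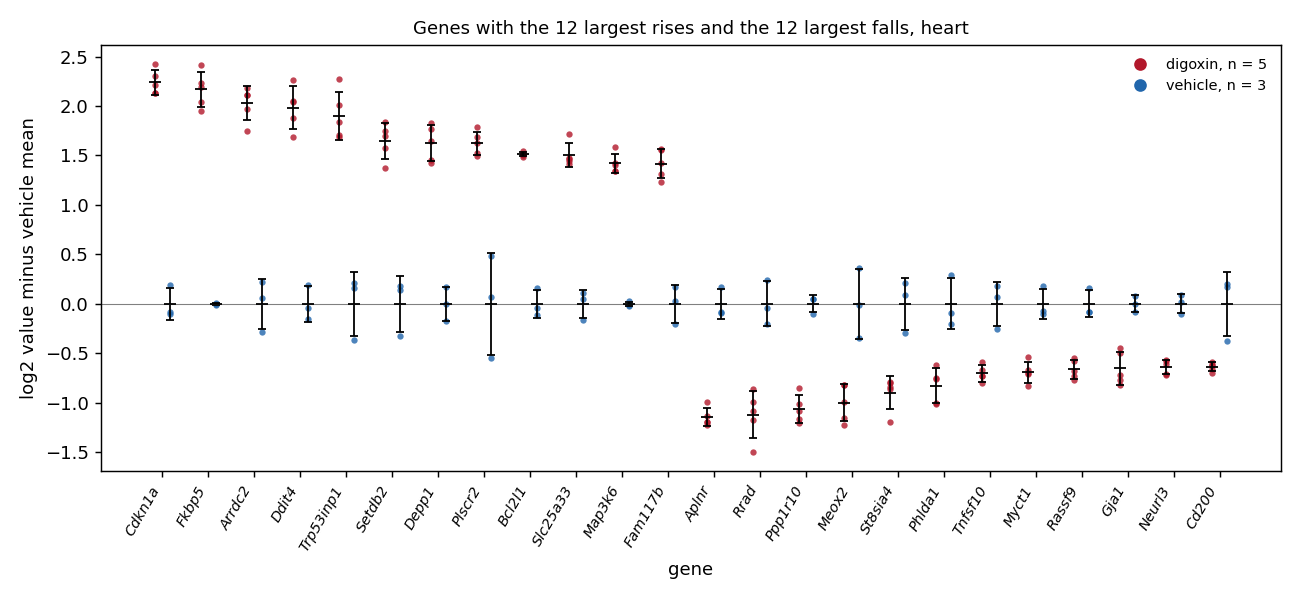
Log2 expression of each gene on each array, minus the mean of the 3 vehicle arrays, for the 12 largest rises and the 12 largest falls among named genes past the test. Red points are the 5 digoxin hearts and blue points the 3 vehicle hearts, with black marks for the mean and SD of each group. No digoxin point overlaps the vehicle points of its gene, which was a condition for choosing these genes.

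At a change of at least 1.5 times, 87 genes rose and 20 fell, and at 2 times 29 rose and 4 fell. The vehicle array of replicate 3 had a wider spread of values than the others, with an interquartile range of 0.216 against 0.0792 to 0.115 for the other 7 arrays. With array weights, which gave that array the lowest weight, 294 genes rose and 320 fell. Leaving out digoxin replicate 2, 3 or 5 or vehicle replicate 2 lowered the count of changed genes from 302 to 170, 174, 166 or 169, and without digoxin replicate 1 the falls numbered 45. The lists past camera numbered 15 without digoxin replicate 4, against 9 with all arrays. Without digoxin replicate 4 and vehicle replicate 3 together, a choice made after the data were seen, 218 genes rose and 282 fell. Of the genes above, calls were lost without single arrays for Meox2 (highest adjusted p = 0.0664, without digoxin replicate 5; also lost without digoxin replicate 3 or vehicle replicate 1 or 2), St8sia4 (0.0562, without vehicle replicate 2; also without vehicle replicate 1), Phlda1 (0.0556, without digoxin replicate 5, and also without digoxin replicate 2 or vehicle replicate 1 or 2), Tnfsf10 (0.0534, without vehicle replicate 2), Gja1 (0.0534, without vehicle replicate 1) and Cd200 (0.139, without vehicle replicate 2, and lost in every such fit but that without vehicle replicate 3).

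Genes known to respond to glucocorticoids rose as a group. All 23 measured members of this list, fixed before the data were examined, had higher means in digoxin hearts. Of these, 16 rose in limma and 7 did not pass, and 21 passed when adjusted over the list alone. The median log2 change was 0.95. Beside Cdkn1a, Fkbp5, Arrdc2, Ddit4 and Map3k6, the members that rose were Mt2 (1.40), Rasd1 (1.26), Zbtb16 (1.11), Nfkbia (1.04), Errfi1 (1.04), Klf15 (1.01), Sgk1 (0.95), Lcn2 (0.90), Cebpd (0.81), Sult1a1 (0.79) and Klf9 (0.51). Rasd1, a Ras-related gene first found as dexamethasone-induced, had an SE of 0.05 and an adjusted p of 1.8e-05 in limma. The 7 members that did not pass were Per1 (0.63), Hif3a (0.50), Pdk4 (0.46), Mt1 (0.46), Angptl4 (0.36), Tsc22d3 (0.30) and Dusp1 (0.09), with adjusted p values of 0.0535 to 0.701. Camera gave an adjusted p of 1.7e-46 for the list, and this was the single list of the 42 tested whose call held when the correlation between genes was estimated (adjusted p = 0.0098 with an estimated correlation). The mean over the list was 0.84 ± 0.07 (SD, n = 5) in digoxin hearts and -0.18 ± 0.03 (SD, n = 3) in vehicle hearts, with an exact permutation p of 0.0179, the smallest these 8 arrays can give, and 0.0774 after adjustment over 26 gene lists. These p values were not particular to this list. The REV-ERB/ROR, HIF-1, p53, ribosome biogenesis and muscle atrophy lists, described below, had the same ones. Some members are shared, since Cdkn1a is also in the REV-ERB/ROR and p53 lists and Ddit4 in the HIF-1 list. Without the members past the test in limma, the mean log2 change of the glucocorticoid list was 0.40. It was 0.09 for REV-ERB/ROR, 0.08 for HIF-1, -0.03 for p53, 0.07 for ribosome biogenesis and 0.12 for muscle atrophy.

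**Figure D2:**
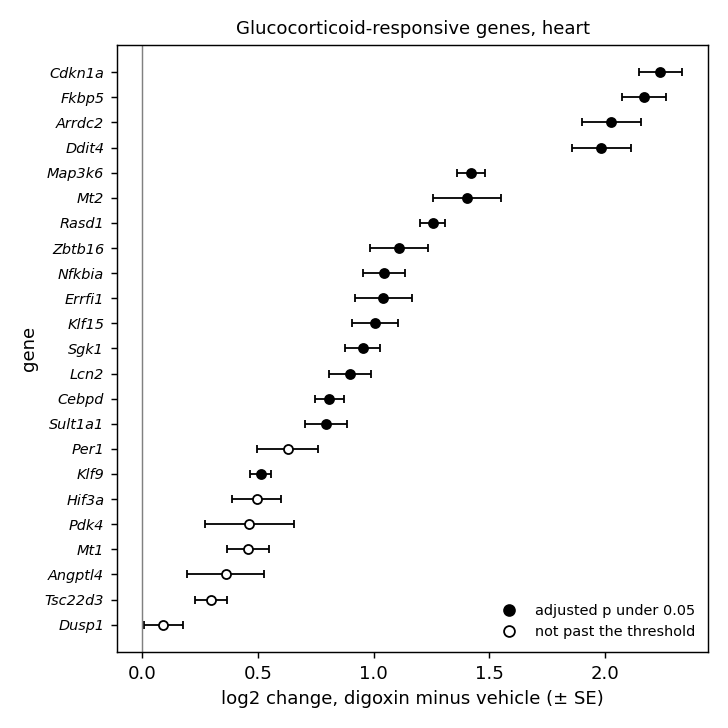
Log2 change (digoxin minus vehicle, horizontal axis) of the 23 measured glucocorticoid-responsive genes, with bars for the SE of the limma fit. Filled points are the 16 genes past the adjusted p threshold and open points the 7 that were not, and every point lies above 0.

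Clock genes moved in different directions. Among 16 measured clock output genes driven by E-box and D-box elements, none rose and 2 fell. These were Dbp, a circadian transcription factor, at -0.53 (SE 0.06, adjusted p = 0.0052), and the period gene Per3 at -0.42 (SE 0.05, adjusted p = 0.0080), both in limma. Adjusted over the list alone, 4 rose and 3 fell, with Per1, Ciart, Usp2 and Wee1 on one side and Dbp, Per3 and Nr1d1 on the other. Nr1d1, the gene of REV-ERB alpha itself, stood at -0.33 (95% interval -0.56 to -0.10, adjusted p = 0.21), and its paralogue Nr1d2 at -0.12 (95% interval -0.29 to 0.06). Neither passed in limma. Camera did not call the list (adjusted p = 0.784).

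Of the 16 measured clock genes with REV-ERB/ROR elements and reported REV-ERB targets, Cdkn1a rose and Il1b, the gene of interleukin 1 beta, fell (log2 change -0.30, SE 0.05, adjusted p = 0.021 in limma). Il1b lost its call without digoxin replicate 2 or 5 or vehicle replicate 1 or 2 (highest adjusted p = 0.0806, without vehicle replicate 2). The other 14 did not pass. Adjusted over the list alone, 3 rose and 1 fell. Arntl, which encodes the clock activator BMAL1 and is a direct REV-ERB target, stood at 0.51 (95% interval 0.26 to 0.75, adjusted p = 0.0693), and it passed without digoxin replicate 1 (adjusted p = 0.0483). Rora stood at 0.29, Npas2 at 0.20, Clock at 0.15, Nfil3 at 0.11 and Cry1 at -0.05. Nlrp3, an inflammasome gene reported as a REV-ERB target, stood at 0.02 (95% interval -0.16 to 0.21). The list missed the camera threshold (adjusted p = 0.0606, and 0.666 with an estimated correlation), and passed it without digoxin replicate 3 (0.0322), 4 (0.0475) or 5 (0.0448). It also passed with each probe set on its own (0.0337), with array weights (0.0273) and without digoxin replicate 4 and vehicle replicate 3 together (0.0470). Per2 was not analysed here.

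Apart from the glucocorticoid list, 7 gene lists passed camera, and each call was lost with an estimated correlation. The muscle atrophy and autophagy list was higher in digoxin hearts (median log2 change 0.12, adjusted p = 9.7e-05, and adjusted p = 0.632 with an estimated correlation), and so was the list of HIF-1 and hypoxia targets (0.05, adjusted p = 0.00099, and adjusted p = 0.632 with an estimated correlation). With 1 array left out, the atrophy median lay between 0.07 (without vehicle replicate 3) and 0.19 (without vehicle replicate 1), and the hypoxia median between 0.03 and 0.11 (without the same arrays). Of 20 atrophy genes, 2 rose, the ubiquitin ligase gene Fbxo32 (0.50, SE 0.08) and the mitophagy receptor gene Bnip3 (0.54, SE 0.08), and 7 rose when adjusted over the list alone. Foxo3 (0.38) and Mstn (0.24) did not pass with all arrays, and both passed without digoxin replicate 1 (adjusted p = 0.0447 for each). Of 20 hypoxia genes, 3 rose, Ddit4, Bnip3 and the glycolytic regulator gene Pfkfb3 (0.74, SE 0.11), and 5 rose when adjusted over the list alone. Ndrg1 averaged 0.39 over probe sets that differed (0.20 and 0.58) and did not pass with all arrays (adjusted p = 0.0418 without digoxin replicate 1). Ddit4 is also a glucocorticoid target, and Hif1a itself stood at 0.21 (adjusted p = 0.407) with probe sets at 0.30 and 0.13. Leaving out single arrays ended the calls of Fbxo32 (highest adjusted p = 0.0823, without vehicle replicate 2; also lost without digoxin replicate 2, 3 or 5 or vehicle replicate 3), Bnip3 (0.055, without vehicle replicate 1) and Pfkfb3 (0.0593, without vehicle replicate 1; also lost without digoxin replicate 5), and without vehicle replicate 3 the atrophy list had an adjusted p of 0.0501 (0.0542 without digoxin replicate 4 as well).

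Of 19 measured p53 targets, 4 rose and none fell. They were Cdkn1a, Trp53inp1, the death receptor gene Fas (0.89, SE 0.10) and Sesn1 (0.73, SE 0.05), a stress-responsive inhibitor of mTORC1. Adjusted over the list alone, 5 rose and 2 fell. The median over the list was 0.02 and the mean 0.28, and with 1 array left out the median lay between 0.01 (without digoxin replicate 1) and 0.06 (without vehicle replicate 2). Camera gave an adjusted p of 0.0154, and adjusted p = 0.632 with an estimated correlation. Without digoxin replicate 1 the adjusted p was 0.0655, and without vehicle replicate 3 it was 0.063. It was 0.144 with quantile normalization, 0.0652 with array weights and 0.0559 without digoxin replicate 4 and vehicle replicate 3 together.

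Inflammatory lists had lower medians in digoxin hearts by small amounts, but their means on single arrays overlapped between the groups. The exact permutation p was 0.0714 for the NF-kB list and 0.143 for the interferon list. The list of NF-kB and inflammatory cytokine genes had a median log2 change of -0.13 over 28 genes (camera adjusted p = 0.0080, and adjusted p = 0.632 with an estimated correlation). In it 2 genes rose, Nfkbia (1.04, SE 0.09), which encodes the NF-kB inhibitor IkB alpha, and the lipocalin gene Lcn2 (0.90, SE 0.09), both also members of the glucocorticoid list. The 2 that fell were Il1b and the macrophage growth factor gene Csf1 (-0.54, SE 0.10, adjusted p = 0.047 in limma). Csf1 lost its call in 7 of the 8 fits that left out an array, all but that without vehicle replicate 3 (highest adjusted p = 0.137, without vehicle replicate 2). Adjusted over the list alone, 2 rose and 3 fell. The interferon-stimulated list had a median of -0.16 over 24 genes (camera adjusted p = 0.0080, and adjusted p = 0.856 with an estimated correlation). None of its members passed in limma with all arrays, and 5 fell when adjusted over the list alone. Its members with the smallest p were Isg15 (-0.22), Oasl2 (-0.46), Cxcl10 (-0.20) and Iigp1 (-0.56). Without vehicle replicate 3, Oasl2 (adjusted p = 0.0132) and Iigp1 (0.0395) passed. The interferon median lay between -0.19 (without vehicle replicate 3) and -0.05 (without vehicle replicate 1) with 1 array left out. The list had a camera adjusted p of 0.415 without vehicle replicate 1, and of 0.505 with the atrial marker mean as a covariate.

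The proteasome list had a median log2 change of 0.05 over 34 subunit genes, and none of them passed in limma or when adjusted over the list alone. Its camera adjusted p was 0.0282, and adjusted p = 0.856 with an estimated correlation. Psmd14 stood at 0.29, Psmd4 at 0.22, Psmc1 at 0.22 and Psmc3 at -0.14. The list of ribosome biogenesis and MYC targets had a median of 0.07 over 24 genes, none of which passed either way (camera adjusted p = 0.0154, and adjusted p = 0.856 with an estimated correlation). Wdr43 stood at 0.25, Rcl1 at 0.21, Pes1 at 0.18 and Mybbp1a at 0.18. With 1 array left out, the proteasome median lay between 0.01 (without vehicle replicate 3) and 0.11 (without vehicle replicate 2), and that of ribosome biogenesis between 0.01 (without vehicle replicate 3) and 0.11 (without vehicle replicate 1). Without vehicle replicate 3 the adjusted p was 0.815 for the proteasome and 0.401 for ribosome biogenesis, and without digoxin replicate 2 it was 0.0611 for the proteasome. Both calls also ended with quantile normalization (0.152 for the proteasome and 0.103 for ribosome biogenesis), with array weights (0.554 and 0.229) and without digoxin replicate 4 and vehicle replicate 3 together (0.376 and 0.528), and the proteasome call with protein-coding genes alone (0.0550).

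Camera called none of the 3 lists of ion transport and excitation. None of 10 measured genes of Na/K-ATPase subunits and sodium extrusion passed in limma, and 1 rose when adjusted over the list alone. Atp1b1, the beta-1 subunit, stood at 0.12 (95% interval -0.02 to 0.27). None of 22 calcium handling genes passed in limma or when adjusted over the list alone. Of 20 potassium, sodium and pacemaker channel and gap junction genes, Kcna5, the gene of the potassium channel Kv1.5, rose (0.60, SE 0.11, adjusted p = 0.040 in limma) and Gja1 fell, and adjusted over the list alone 3 rose and 3 fell. Kcna5 lost its call in 6 of the 8 fits that left out an array, all but those without digoxin replicate 3 and vehicle replicate 2 (highest adjusted p = 0.114, without digoxin replicate 5). Camera adjusted p values for these 3 lists were 0.276, 0.427 and 0.789.

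Of 26 immediate early genes, 3 rose and 1 fell in limma, and 5 rose and 1 fell when adjusted over the list alone. The mRNA decay factor gene Zfp36 rose by 1.14 (SE 0.13), the matricellular gene Ccn1 by 1.06 (SE 0.16) and Gadd45b by 0.80 (SE 0.13), and Ier3 stood at -0.55 (SE 0.07). Camera did not call this list (adjusted p = 0.093), but it passed without digoxin replicate 2 (0.0480), 3 (0.0431) or 5 (0.0205), and without digoxin replicate 1 its direction turned to lower (0.892). Ccn1 lost its call without digoxin replicate 2 or vehicle replicate 1 or 2 (highest adjusted p = 0.0847, without vehicle replicate 2), and Gadd45b without digoxin replicate 1 or 2 or any 1 vehicle array (0.0752, without vehicle replicate 2). Herpud1, a gene of endoplasmic reticulum protein degradation, rose by 0.71 (SE 0.05) as the single member past the test among 25 genes of the unfolded protein and integrated stress response, and 1 rose when adjusted over the list alone. Col4a1, a basement membrane collagen gene, rose by 0.47 (SE 0.06) as the single member past the test among 22 genes of extracellular matrix and TGF-beta response, where 2 rose when adjusted over the list alone.

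No member passed in limma among 21 genes of cardiac stress and the fetal programme, 19 heat shock genes, 16 NRF2 targets, 25 genes of fatty acid oxidation, 19 of glycolysis, 34 of oxidative phosphorylation, 15 of cholesterol synthesis, 37 ribosomal protein genes, 25 proliferation genes and 12 T helper 17 genes. Adjusted over the list alone, these 10 lists had no changed member, apart from 1 ribosomal protein gene that fell and 3 T helper 17 genes, of which 2 rose and 1 fell. Camera did not call any of the 10 lists with the default settings, and called 3 of them higher in other settings. Fatty acid oxidation passed without digoxin replicate 1 (adjusted p = 0.0255) or 4 (0.00629) or vehicle replicate 1 (0.00211), with each probe set on its own (0.0324), with array weights (0.00147) and without digoxin replicate 4 and vehicle replicate 3 together (0.0257). Proliferation passed without digoxin replicate 2 (0.0351), 3 (0.0256) or 5 (0.0190), with each probe set on its own (0.0455) and with the atrial covariate (0.00114), and glycolysis without digoxin replicate 4 (0.0115). The proliferation mean was 0.53 in digoxin replicate 4, the array with high thymus and T cell markers, and below 0 in every other array, and without that array the direction turned to lower (adjusted p = 0.907). Nppa, the atrial natriuretic peptide gene, stood at -0.51 (95% interval -1.37 to 0.35) and Nppb, the brain natriuretic peptide gene, at -0.43 (95% interval -0.77 to -0.09, adjusted p = 0.28 in limma). The median, mean and camera direction differed in sign for 9 of the 42 lists, none of which passed. These were calcium handling, channels, heat shock, oxidative phosphorylation, extracellular matrix, ribosomal proteins, ventricular cardiomyocytes, macrophages and neurons.

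The makeup of the tissue was followed with 17 lists of cell type markers. None of the 17 list means differed between the groups in the exact two-sided permutation test at a p of 0.05, and the smallest was that of the B cell markers (-0.09, exact p = 0.0714). The exact permutation test gave p = 0.0286 for the B cell markers without digoxin replicate 4 and p = 0.0476 without vehicle replicate 3 for the erythroid list, which held 1 measured gene. Atrial cardiomyocyte markers varied widely from heart to heart. Their mean was 0.26, -0.23, 0.82, 1.40 and -0.32 in digoxin replicates 1 to 5, and 1.92, 1.44 and 0.17 in vehicle replicates 1 to 3 (difference -0.79, exact p = 0.214). Camera called this list lower (median -0.73, adjusted p = 0.0181, and adjusted p = 0.856 with an estimated correlation), and none of its 10 genes passed in limma or when adjusted over the list alone. The atrial call was lost without digoxin replicate 2 (adjusted p = 0.0609) or 5 (0.0596) and without vehicle replicate 1 (0.415) or 2 (0.117), and was stronger without vehicle replicate 3 (1.2e-06). Its median lay between -1.18 (without vehicle replicate 3) and -0.33 (without vehicle replicate 1) with 1 array left out. Nppa is a member of this list. The ventricular cardiomyocyte markers had an exact permutation p of 0.946. In digoxin replicate 4 the T and NK cell markers averaged 0.98 and the thymus markers 1.06, against means of no more than 0.08 in the other digoxin hearts for both. The adipocyte markers (0.58) and mesothelial markers (0.52) were also highest there among the digoxin hearts. Camera called the mesothelial (adjusted p = 0.00431), B cell (0.0112) and fibroblast (0.0283) markers lower without digoxin replicate 4, the B cell markers also without vehicle replicate 2 (0.0212) and the fibroblast markers without vehicle replicate 3 (0.0247). With array weights it called the fibroblast (0.00934) and macrophage (0.0378) markers lower. Without digoxin replicate 4 and vehicle replicate 3 together it also called the fibroblast (0.00158) and macrophage markers lower, and the atrial call was stronger (6.0e-09). Within the endothelial markers, Esam rose (0.46) and Eng fell (-0.47), both chosen here after their values were seen, and adjusted over the list alone 3 rose and 2 fell.

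**Figure D3:**
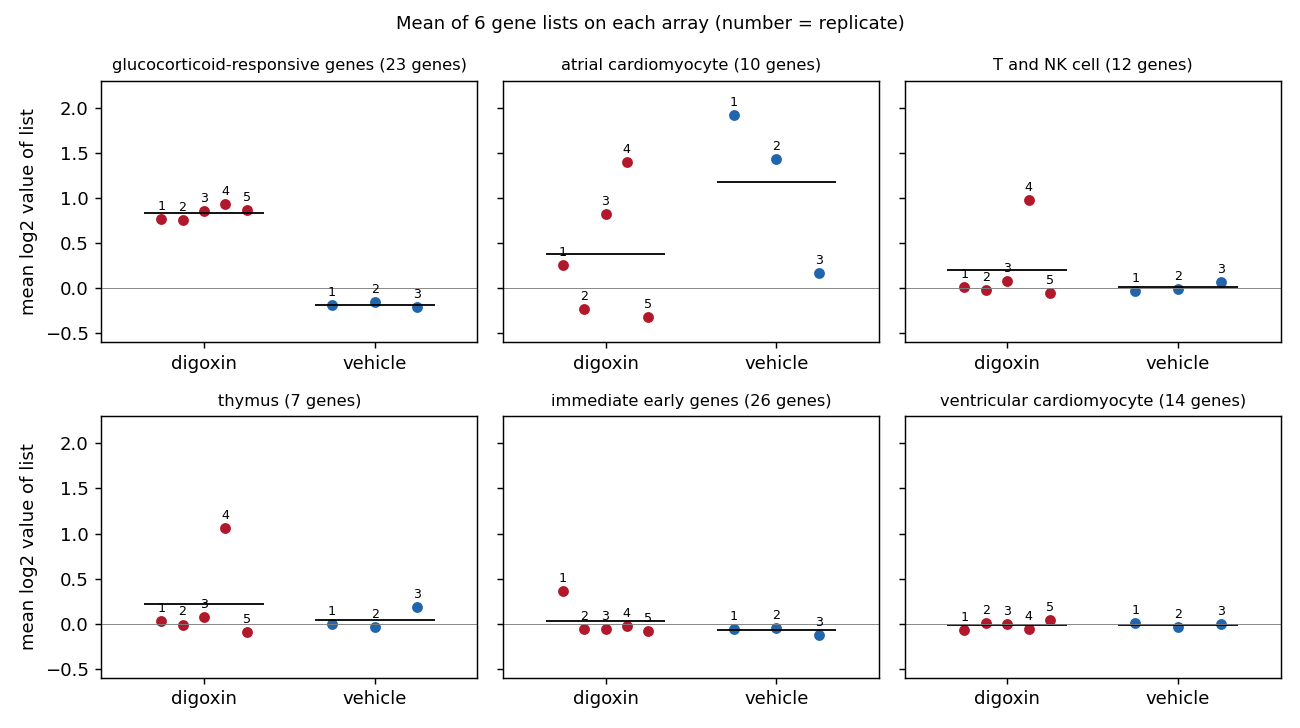
Mean log2 value of 6 gene lists on each array (vertical axis), with digoxin hearts in red, vehicle hearts in blue, the replicate number beside each point and a black line at the group mean. The glucocorticoid-responsive genes separate the groups, the atrial markers vary within both groups, and the T and NK cell and thymus markers are high in digoxin replicate 4.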

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

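The tests of vehicle replicate 3, p53 and FOXO targets, thymus tissue, blood leukocytes and the atrial markers in this part were chosen after the results were seen. The group of digoxin arrays was searched for single arrays far from the other 4 in 116 results (72 genes, 43 list means and the spread of the arrays). In 12 of them the gap exceeded the critical value, where chance gives about 1 in 20, or 5.8.

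Digoxin replicate 1 stood apart in several stress genes. Relative to the mean of the other 4 digoxin arrays, the mean of the immediate early genes was higher there by 0.42, Ccn1 by 0.68, Slc25a33 by 0.27 and the mean of the p53 targets by 0.0896, while St8sia4 was at -0.37 and Foxo3 at -0.27. Digoxin replicate 4 stood apart in lymphocyte and other genes. There the thymus markers were higher by 1.06, the T and NK cell markers by 0.98, the proliferation genes by 0.56, Nfkbia by 0.37 and the B cell markers by 0.10, and the proteasome mean was at -0.0893.

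The rise of the glucocorticoid-responsive genes was weighed first. A chance split of the arrays is argued against for the count of changed genes and for this list, since only 1 of the 56 splits of the 8 arrays, the real one, gave 302 genes (highest other 2) and 16 list members (highest other 0). Neither the wide vehicle replicate 3 nor atrial tissue accounts for it. Without vehicle replicate 3, 16 members rose, and with the atrial covariate the median was 1.04. A p53 response was weighed with the p53 targets outside the list, which had been seen before in the fixed p53 list. Their median was 0.0214 (SE 0.0412). Among them Trp53inp1 (1.90), Fas (0.89) and Sesn1 (0.73) rose, and the other 15 did not pass. These values argue against a rise across p53 targets as the whole cause. A p53 response limited to some targets stays open as a part of it. Raised glucocorticoid signalling may have a part, as a hypothesis. In 16 other glucocorticoid-induced genes, listed before their values were seen, the median was 0.29 (SE 0.13), and 4 rose. Camera gave p = 4.0e-08 for them, and 0.0036 with an estimated correlation. FOXO activity stays open, since 14 other FOXO targets had a median of 0.16 (SE 0.07), and 3 rose. For these camera gave p = 3.0e-08, and 0.0083 with an estimated correlation. Of the 14, 9 had been seen before in the fixed lists, with all that rose (Sesn1, Fbxo32 and Bnip3). These p values therefore do not decide on FOXO activity. The members not seen before were Sesn3 (0.17), Ccng2 (0.10), Insr (0.08), Eif4ebp1 (0.03) and Sod2 (-0.01), and none of them passed in limma. Hormone levels were not measured here, and a stress response to the injected drug and a direct effect on the heart both stay open. An effect of array order cannot be told apart from treatment either, since the vehicle arrays came first in the labels.

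High T cell genes in digoxin replicate 4 were weighed next. Immature thymocyte genes had a median 1.15 (SE 0.32) above the mean of the other 7 arrays, with members from -0.22 (Cd1d1) and -0.03 (Ptcra) to 2.31 (Cd8b1). Of the 10, 7 had been seen before in the fixed thymus list, so the median does not decide by itself. The members not seen before, Satb1 (1.66), Bcl11b (1.24) and Arpp21 (0.97), were all high on this array. The B cell and neutrophil markers were at a median of -0.0184 (SE 0.0296). These fixed lists had been seen before too, so this value does not decide on blood leukocytes. The B cell mean was itself flagged there, higher by 0.10 than in the other digoxin arrays. Thymus tissue carried over with the heart stays open, and so does other tissue, since the adipocyte (0.58) and mesothelial (0.52) markers were high there too. A biological difference of this mouse was not tested.

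The third pattern was the spread of atrial genes. The 10 markers deviated together within groups, with a mean pairwise correlation of 0.75 across the arrays, in line with hearts that kept different shares of atrial tissue. An effect of digoxin on these genes cannot be told apart from that, since the exact permutation p of their mean was 0.214 and the groups overlap. For the number of gene and marker lists past camera, chance cannot be excluded: 36 of the 56 splits gave at least 9 lists, with 22 as the highest other.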

How the results depend on the processing

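The filters on dim genes and the choice of the probe set with the highest mean could not be run on centred values. The counts of 302 changed genes, 210 up and 92 down, 16 glucocorticoid members and 9 lists moved by over 1.5 times in the following settings, and beyond the settings' construction the cause was not tested. Quantile normalization gave 319 rises. Trend and robust variance gave 127 genes (95 up, 32 down), array weights 614 (320 down, 48% up) and ordinary least squares 100 (76 up, 24 down). The looser threshold gave 493 (327 up, 166 down) and the added fold minimum 107 (87 up, 20 down). Without digoxin replicate 4 and vehicle replicate 3 together, tried after seeing the data, there were 500 (282 down), of which 235 were among the 302. Camera with an estimated correlation called 1 list (glucocorticoid), fry 3 (also p53 and REV-ERB/ROR) and fgsea 5 (glucocorticoid, p53, HIF-1, interferon, atrophy). With the atrial covariate the atrial list had a median of 0.00067, by construction.

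With 1 array left out the counts ranged from 166 to 374 genes, 123 to 185 up, 29 to 189 down, 16 to 17 glucocorticoid members, 6 to 15 lists (15 without digoxin replicate 4) and 0 to 1 marker lists. Of the 43 named genes past the test, 29 passed in every such fit. With the atrial covariate 8 named genes lost their call and 1 gained it, and with each probe set on its own 3 lost it.

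As a fixed replicate block, the title numbers gave 12 genes (11 up, 1 down), 6 glucocorticoid members and 15 lists. The numbers of the sample descriptions gave 7 genes (7 up, 0 down), 5 members and 7 lists, and a random block on the title numbers 256 genes. These numbers do not pair the arrays: deviations of arrays with the same title number correlated at -0.20, -0.02 and 0.02, and by description number at 0.02, 0.04 and -0.15. Depth cannot be judged, since centred values hold no signal over background.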

Other observations

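Of the 302 genes that changed, 266 were in no fixed list. The genes in this part lie outside the rule for named genes and were chosen after their values were seen. Among them, Eng and Esam belong to the fixed endothelial marker list. Nt5e, the ecto-5'-nucleotidase that makes extracellular adenosine, rose to 2.54 times the vehicle level (log2 change 1.35, SE 0.12, adjusted p = 0.0013 in limma). Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, rose by 1.27 (SE 0.16) and the lipid droplet gene Plin4 by 0.82 (SE 0.07). The alpha-arrestin genes Arrdc3 (1.27, SE 0.11) and Txnip (0.85, SE 0.11) rose along with Arrdc2. Gadd45g rose by 1.28 (SE 0.10), Fam107a by 1.26 (SE 0.06) and Cited2, a transcriptional co-regulator that competes with HIF-1 alpha for its co-activators, by 0.94 (SE 0.05).

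Vegfc, a lymphatic growth factor gene, stood at -0.55 (SE 0.07), the VEGF co-receptor gene Nrp1 at -0.52 (SE 0.08), the venous transcription factor gene Nr2f2 at -0.48 (SE 0.09) and Eng, an endothelial TGF-beta co-receptor gene, at -0.47 (SE 0.09), each past the test in limma. The endothelial gene Esam rose by 0.46 (SE 0.09), and the mean of the endothelial marker list differed by 0.01 (exact permutation p = 0.875). The mitochondrial co-activator gene Ppargc1b stood at -0.53 (SE 0.08) and Sox9 at -0.54 (SE 0.08). No test was run on these genes as a group.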
